A study of Mus musculus with 6 samples.

How the data were processed

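The samples were 6 samples of RAW264.7 cells treated with RANKL and M-CSF, 3 labelled control and 3 labelled RhoA knockout. Total RNA was extracted with Trizol and made into libraries with an Illumina kit, per the labels' protocols. The values used are the whole-number counts per gene that the authors deposited in 1 table of 55487 genes, without normalization. The reads were aligned to GRCm38, per the submitters' processing notes. The aligner, the counting tool, its strand setting and its treatment of reads that match several places are not given in the sources used here. Every value column of the table was matched to a sample by its name, and 0 columns were left out.

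The counts themselves show 2 features of how they were made. Counts at multiples of 4 up to 40 were 1.32 to 1.45 times as frequent as their neighbours would give, so a read pair may have entered more than once at some genes. Genes and their near-identical copies often held close to equal counts, such as mt-Atp6 and its copy Gm10925 at a ratio of 0.989 to 1.012, so reads that match both may have been counted for both or shared between them. Genes with such copies are given as uncertain. For each of 145 named genes, a transcript was compared with all annotated transcripts by blastn 2.17.0, and 25 had a matching gene at 95% identity or more over at least 200 bp that held 10% or more of their count. Counting intervals and floors cover counting error only.

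Gene IDs were matched to GENCODE M21 on GRCm38. Of the IDs, 54435 matched with their version and 55227 had a symbol, while 260 had none. Coordinates are those of GENCODE M21. Library totals were 79918899, 60198645 and 66104600 counts for the control libraries and 71777994, 79639979 and 81830819 for the others, and 20038 genes had a count. A floor of 3 counts corresponds to 0.037 to 0.05 CPM. No 2 libraries agreed within sampling noise. The chi-square per degree of freedom over genes was 23.6 between control replicates 1 and 2, and 30.5 between knockout replicates 1 and 2. It was 108.9 or more between control replicate 3 and the other controls, and 97.8 or more between knockout replicate 3 and the others of its group.

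The main comparison was edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr with its defaults, estimateDisp, glmQLFit with robust fitting and glmQLFTest, with Benjamini-Hochberg adjustment at 0.05 over 12930 genes. The common biological coefficient of variation was 0.32. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled. Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 31 of 38 lists that had at least 5 measured members, and with fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Rhoa was left out of all lists. The lists cover RhoA effectors, their regulators, SRF/MRTF, immediate early and YAP/TAZ target genes, osteoclast genes and their repressors, adhesion, matrix, v-ATPase and lysosomal genes, inflammatory, interferon, MHC, macrophage and alternative activation genes, proliferation, p53, glycolysis, oxidative phosphorylation and cholesterol genes, stress responses, ribosomal proteins, RNA quality genes and markers of 7 other cell types. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

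The rule for named genes took Rhoa, then the 10 largest rises and 10 largest falls with an adjusted p under 0.05, an average log2 CPM of at least 3 and all 3 libraries of a group on 1 side of the other 3, leaving out predicted or clone-named models and pseudogenes. From each list it took up to 4 called members with the smallest p, or the 2 most abundant where none was called. Genes named outside the rule are said to be so. Copies were sought for them in the same way. The result of 1 of the tested lists and those of some named genes are not reported here.

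The procedure was tested on simulated data for the comparison of the libraries labelled RhoA knockout with control, in 10 data sets of 12930 genes with the real means, library sizes and dispersions and 200 changed genes each. It recovered 11.5% of 1.5-fold, 48.1% of 2-fold and 85.3% of 4-fold changes. The changed genes, and those of the simulated lists below, were drawn only from genes above a minimum expected count. These shares therefore leave out sparsely counted genes. False calls made up 7.9% of all calls, from 4.4 to 14.9% per data set, which is above the nominal 5%. With dispersions drawn from the trend over expression the share was 5.5%. Of the unchanged genes 4.7% had an unadjusted p under 0.05 in the first case. Far fewer genes passed in these data sets than in the real comparison, where more calls loosen the cutoff of the adjustment. The shares recovered and falsely called therefore do not carry over to it. Camera called 5 of 5 simulated lists of 30 genes raised 1.5-fold and 0 of 20 unchanged lists. Simulated genes were drawn independently, so this does not test the preset correlation for real lists whose members move together. The estimated correlation of the oxidative phosphorylation list, for instance, was 0.432.

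The alternatives were RLE, upper-quartile and no scaling factors, no filter and a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust fitting, the replicate number as a block, each library left out in turn and a test against a 1.5-fold change, and for lists an estimated correlation and fry. Added after the data were seen were a length correction per library by loess with a span of 0.5 on log2 exon length, removal of the 10 genes with the most counts, and counts divided by 4. An exact permutation test of 3 against 3 samples cannot go below a two-sided p of 0.1.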

Results

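RNA from 6 samples of RAW264.7 cells, a mouse macrophage line that can form osteoclasts, was sequenced and counted per gene. All 6 samples had received RANKL and M-CSF, the cytokines that drive osteoclast formation. The labels put 3 samples in a control group, called untreated in the study's design text. They put 3 in a group in which RhoA, a small GTPase that controls the actin cytoskeleton, had been targeted with Cas9. The latter are titled SMART-Cas9. No group had Cas9 without the targeting of RhoA, so effects of the Cas9 treatment cannot be told apart from those of the edit. The study asked what loss of RhoA in macrophages does in the setting of bone destruction in rheumatoid arthritis. The totals per library ran from 60198645 to 81830819 counts. Nothing in the labels says that the 3 samples of a group were grown separately, so the p-values measure only the spread between these samples, which may be technical. A few genes took most of the counts. The 10 most abundant genes held 62.5, 63.2 and 62.0% of the control libraries and 44.1, 45.6 and 47.8% of the others. Spp1, which encodes osteopontin, alone held 32.81, 33.95 and 32.81% of the control counts.

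Rhoa, the targeted gene (ENSMUSG00000007815.13, chromosome 9, 108306129 to 108337934 on the plus strand of GRCm38), was not lower in the libraries labelled RhoA knockout. It held 1655, 1510 and 1440 counts in the control libraries and 2805, 2670 and 2395 counts in the libraries labelled RhoA knockout. In TMM-scaled CPM this was 23.9 ± 2.22 (SD, n = 3) against 31.9 ± 2.18 (SD, n = 3), a log2 fold change of 0.41 ± 0.12 (SE) with an edgeR adjusted p of 0.0136. Every library labelled RhoA knockout lay above every control library. Without control replicate 1 the adjusted p was 0.0645, and without knockout replicate 1 it was 0.0741, with a log2 fold change of 0.34 in both cases. The level checks the label only where an edit lowers the transcript, and a frameshift can leave the level as it was. The groups are named by their labels from here on, and each direction below is that of the libraries labelled RhoA knockout against the control libraries. Of the transcripts of other genes that match Rhoa, the pseudogene Gm12844 held at most 4 counts in a library.

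**Figure D1:**
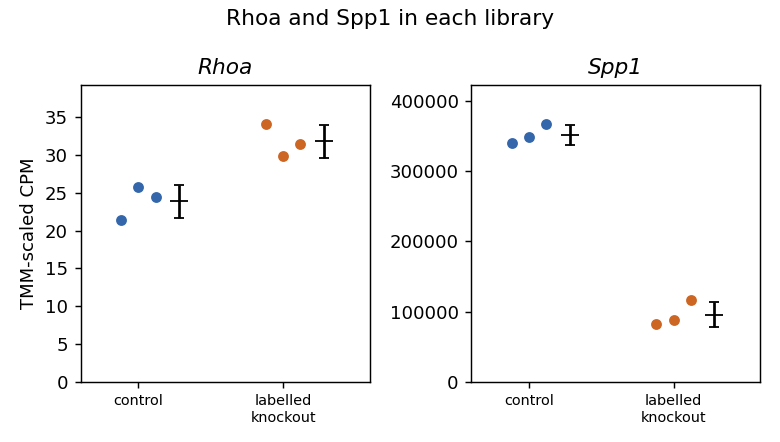
TMM-scaled CPM of Rhoa and Spp1, each on a linear axis that starts at 0. Points are the 3 libraries of each group, and the bars beside them are the mean and SD. Rhoa lies at 23.9 CPM in the control libraries and at 31.9 CPM in the libraries labelled RhoA knockout, while Spp1 lies lower there.

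Between the groups 5592 of 12930 genes tested passed an edgeR adjusted p of 0.05, with 2713 higher and 2879 lower in the libraries labelled RhoA knockout, in which Rhoa itself was not lower. At least 2-fold changes were found for 1442 higher and 1901 lower genes. The changes given next are the 10 largest falls and 10 largest rises that met the rule for named genes, which asks for an average log2 CPM of at least 3. Csf3, the granulocyte colony-stimulating factor, fell from 1397 ± 805.6 to 0.21 ± 0.077 CPM (SD, n = 3 each; log2 fold change -12.69 ± 0.70, SE; adjusted p = 3.03e-05). Ccl7, a monocyte-attracting chemokine, fell from 3946 ± 403.7 to 0.759 ± 0.342 CPM (-12.34 ± 0.36, adjusted p = 2.45e-09). The value of Csf3 was -12.10 without control replicate 3. Ccl2 and Ccl3, chemokines as well, fell from 5113 to 17.6 CPM and from 16240 to 121.2 CPM. Ptgs2, the inducible cyclooxygenase, had a log2 fold change of -9.35 ± 0.72, Lcn2, an iron-carrier-binding protein of innate immunity, of -8.52 ± 0.43, and Il1rn, the interleukin-1 receptor antagonist, of -6.94 ± 0.26. Pdpn, which encodes podoplanin, had a log2 fold change of -9.61 ± 0.77. The sizes for Csf3, Ptgs2, Lcn2 and Pdpn rest on few counts in the libraries labelled RhoA knockout, such as 10, 22 and 20 for Csf3. Ptgs2 was at -10.21 without knockout replicate 3 and Pdpn at -10.90 without knockout replicate 2. Upp1, a uridine phosphorylase, held 0, 18 and 0 counts in the libraries labelled RhoA knockout against 1539, 1424 and 2227 in the controls. Urah held 3 counts in all 3 libraries labelled RhoA knockout together, all of them in replicate 3. Its fall is therefore given as a ratio between the groups of summed counts over summed TMM-scaled totals. This ratio was 4280 with a 95% counting interval of 1460 to 20800.

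Among the rises, Gas7, a growth-arrest gene linked to actin, rose from 102.2 ± 14.2 to 2150 ± 159.6 CPM (SD, n = 3 each; log2 fold change 4.40 ± 0.15, SE; adjusted p = 2.57e-09). Cx3cr1, the fractalkine receptor, rose from 1.16 ± 0.627 to 16.7 ± 1.74 CPM (3.85 ± 0.31, adjusted p = 1.33e-06). Tmem176b, Crip1, Igsf6 and Bnip3, of which Bnip3 is a hypoxia-induced mitophagy receptor, had log2 fold changes of 4.06, 3.76, 3.74 and 3.56. The mitochondrially encoded mt-Nd3, mt-Nd1 and mt-Cytb, subunits of the respiratory chain, rose by 4.60, 4.29 and 3.81 on the log2 scale, and mt-Nd3 is uncertain because its pseudogene copy Gm28438 shares its sequence. Hist1h2ap, with a log2 fold change of 3.83 ± 0.52, is likewise uncertain because 9 matching histone genes each held at least 10% of its count in a library. Scaling mattered for the balance of directions. With library totals alone 59.8% of calls were higher, against 48.5% with TMM, and the median log2 fold change of all genes moved from -0.03 to 0.15.

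**Figure D2:**
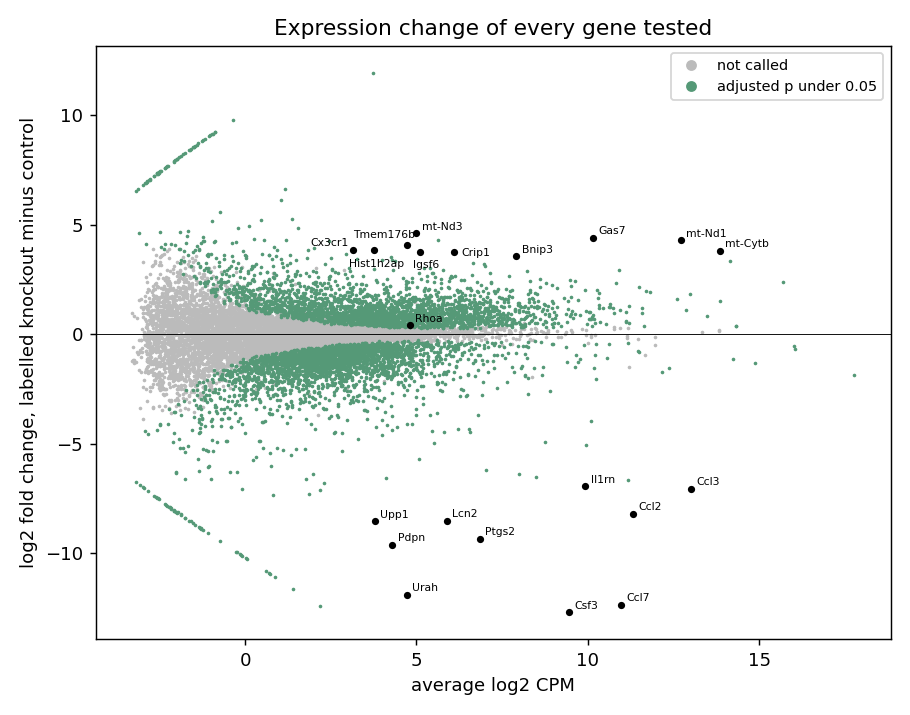
Log2 fold change of the libraries labelled RhoA knockout minus control against average log2 CPM for the 12930 genes tested, with called genes in green. Black points are Rhoa at 0.41 and the 10 largest rises and 10 largest falls that met the rule for named genes, which asks for an average log2 CPM of at least 3. The straight edges at the left are genes without a count in a whole group, whose fitted values are no estimates of size.

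Of the gene lists, the interferon and inflammatory lists had the smallest camera p-values. Of 40 measured inflammatory cytokines and NF-kB target genes, 29 were lower, 4 higher and 7 not called (29 and 4 adjusted over the list alone), with a median log2 fold change of -2.27. Its camera adjusted p was 9.68e-30, and 0.0108 with an estimated correlation. Tnf fell from 140.5 ± 11.2 to 7.06 ± 0.579 CPM (SD, n = 3 each), and Ccl4 from 4554 ± 1281 to 45.6 ± 3.92 CPM. Of 49 measured genes of the type I interferon response, 45 were lower, none higher and 4 not called (46 lower adjusted over the list alone), with a median of -2.24. Camera gave an adjusted p of 8.63e-38, and 0.0108 with an estimated correlation. Rsad2, the antiviral protein viperin, fell from 65.5 ± 12.9 to 1.26 ± 0.014 CPM, and Ifit2, Xaf1 and Isg20 had log2 fold changes of -4.39, -3.57 and -3.69. These were the only 2 of 31 tested lists still called with an estimated correlation. With the correlation preset at 0.01, camera called 12 lists, of which 6 were higher and 6 lower. The fry test, which does not compare a list with other genes, called these and others, 25 in all.

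**Figure D3:**
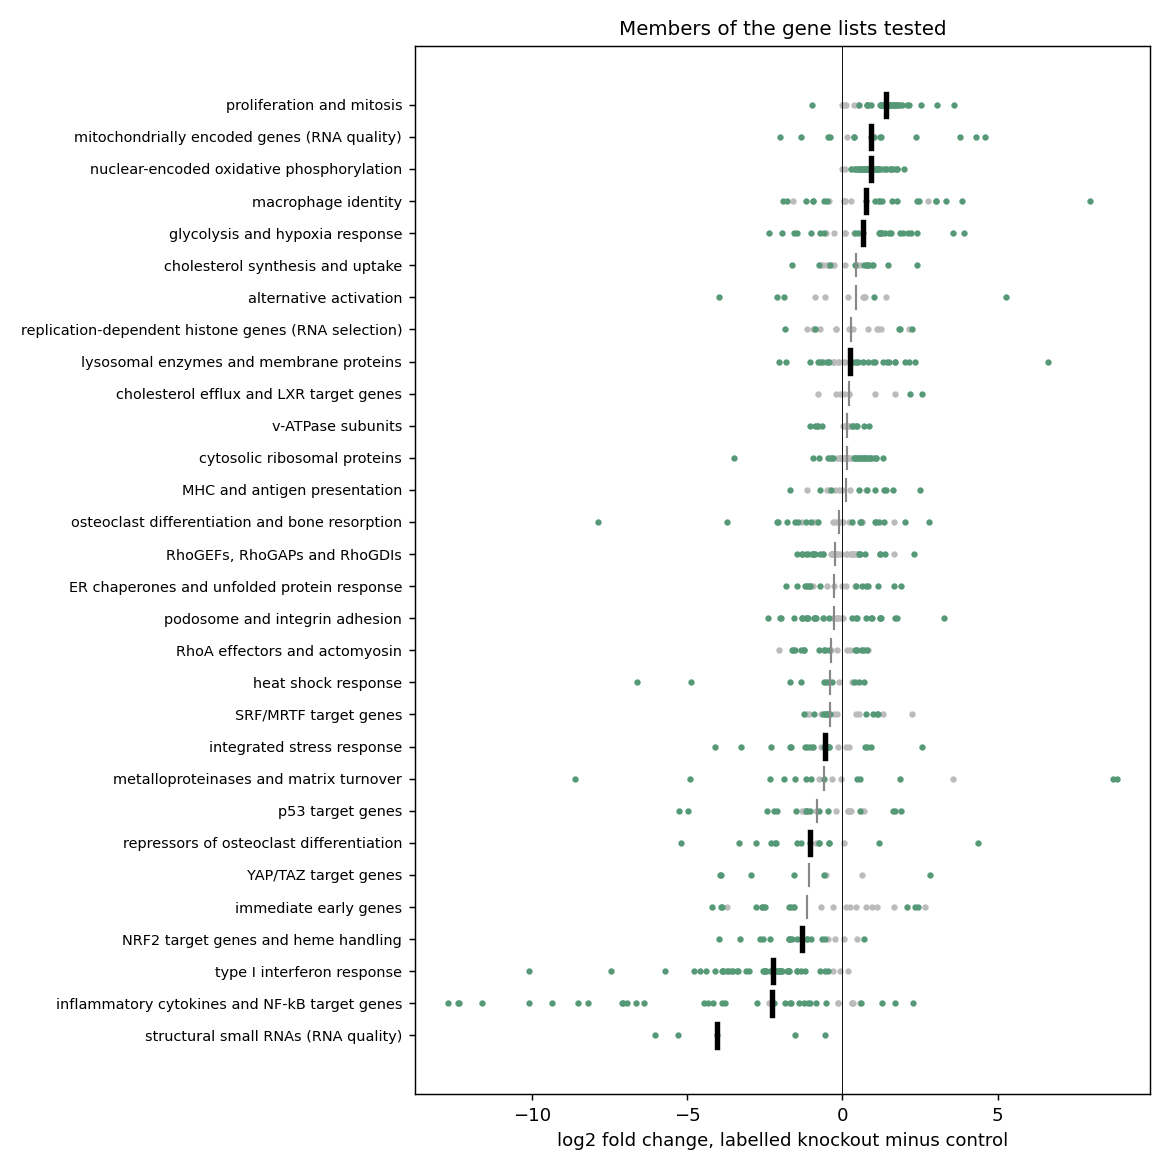
Log2 fold change, libraries labelled RhoA knockout minus control, of every measured member of 30 tested lists, with called genes in green and others in grey. Bars mark list medians, thick and black where the camera adjusted p at a preset correlation of 0.01 was under 0.05. The type I interferon list lies at a median of -2.24 and the proliferation list at 1.42.

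The genes of osteoclast differentiation and bone resorption were called in both directions. Of 32 measured members 9 were higher, 10 lower and 13 not called, the same as adjusted over the list alone, with a median of -0.11, although the sign of the camera test was positive (adjusted p = 0.817), as was that of fry (adjusted p = 0.00652). With a length correction chosen after the data were seen, the median was 0.02. Trem2 and Tyrobp, a receptor and its signalling adaptor, rose from 35.8 ± 2.03 to 246.3 ± 27.7 CPM and from 244.3 ± 15.0 to 614.5 ± 98.8 CPM (SD, n = 3 each). Car2, the carbonic anhydrase that supplies protons for resorption, rose by 2.03 ± 0.13 on the log2 scale, and Tcirg1, a subunit of the osteoclast proton pump, had a log2 fold change of -1.16 ± 0.12. Some classical markers were chosen here after their values were seen. Of these, Ctsk had a log2 fold change of 1.10 ± 0.18 (adjusted p = 0.000324) and Mmp9 of -2.06 ± 0.27 (6.18e-05). Acp5 had one of -1.43 ± 0.34 (0.00509) and Nfatc1 of 0.64 ± 0.27 (0.0742, but 0.0126 with the length correction). Their levels were low in both groups. Ctsk went from 5.81 CPM in the controls to 12.45 CPM and Mmp9 from 6.61 to 1.59 CPM. Acp5 went from 2.22 to 0.823 CPM and Nfatc1 from 2.3 to 3.67 CPM. The repressors of osteoclast differentiation fell, with 13 of 17 lower and 2 higher, the same adjusted over the list alone, and a median of -1.03. For the list, camera gave an adjusted p of 5.28e-05, and 0.21 with an estimated correlation. Irf8 fell from 49.8 ± 1.39 to 11.5 ± 1.30 CPM, and Irf7, Id3 and Id1 had log2 fold changes of -2.78, -2.29 and -5.20. Irf7 is also an interferon-induced gene.

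Lists of adhesion, matrix and acidification held genes called in both directions. Of 36 podosome and integrin adhesion genes 12 were higher and 15 lower (12 and 16 adjusted over the list alone; median -0.28, camera adjusted p = 0.663, fry adjusted p = 0.00467). Lsp1, an actin-binding protein of leukocytes, rose from 18.7 ± 1.86 to 180.2 ± 8.70 CPM, and the integrin chain Itga5 fell from 42.2 ± 0.512 to 8.02 ± 0.915 CPM (SD, n = 3 each). Of 17 metalloproteinases and matrix turnover genes 5 were higher and 8 lower (6 and 8 adjusted over the list alone; median -0.59, mean 0.06, camera adjusted p = 0.153, but 0.0474 with the stricter filter and 0.0316 with counts divided by 4, the latter chosen after the data were seen; fry adjusted p = 0.000813 with a negative sign). Spp1 (chromosome 5, 104435118 to 104441050) fell from 352300 ± 14340 to 95760 ± 17720 CPM, a log2 fold change of -1.88 ± 0.16 (adjusted p = 2.58e-06), and Adam8 had one of -1.51 ± 0.11. Of 17 v-ATPase subunits 6 were higher and 5 lower, the same adjusted over the list alone (median 0.16, mean -0.02, camera adjusted p = 0.907). The lysosomal list rose, with 16 of 38 higher and 8 lower (16 and 9 adjusted over the list alone) and a median of 0.26. The camera adjusted p was 0.0152, and 0.317 with an estimated correlation. Ctsa, Ctss and Lgmn, lysosomal peptidases, rose by 2.33, 2.02 and 2.15 on the log2 scale, while Ctsl had a log2 fold change of -2.05.

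None of the lists of RhoA effectors, regulators and downstream target genes was called by camera with the preset correlation, while fry called 3 of those below as lower. For the effectors and the regulators the median turned to 0.16 with the length correction, chosen after the data were seen. Of 23 RhoA effectors and actomyosin genes 5 were higher and 10 lower, the same adjusted over the list alone (median -0.36, camera adjusted p = 0.36, fry adjusted p = 0.00194). The formin Diaph1 had a log2 fold change of -1.51 ± 0.16 and the actin-severing Cfl1 of 0.71 ± 0.13. Of 43 exchange factors, GTPase-activating proteins and dissociation inhibitors 7 were higher and 11 lower (6 and 11 adjusted over the list alone; median -0.23, camera adjusted p = 0.654, fry adjusted p = 0.0219). Arhgdib, a dissociation inhibitor of leukocytes, rose by 1.38 ± 0.13 and Srgap2 had a log2 fold change of -1.45 ± 0.16, or -0.85 with the length correction. Of 21 SRF/MRTF target genes 4 were higher and 8 lower (5 and 8 adjusted over the list alone; median -0.40, camera adjusted p = 0.817), with Tpm4 at 1.14 and Actg1, uncertain because of its pseudogene copy Gm12715, at -1.25. Of 26 immediate early genes 3 were higher and 10 lower (3 and 11 adjusted over the list alone; median -1.12, camera adjusted p = 0.153), with Zfp36 at -2.59 and Fos at 2.08. Of 8 measured YAP/TAZ target genes 1 was higher and 5 lower, the same adjusted over the list alone (median -1.07, camera adjusted p = 0.654, fry adjusted p = 0.0132), with Gadd45b at -3.92 (-4.56 without knockout replicate 1), Axl at -2.94, Myof at -1.56 (-0.97 with the length correction) and Birc5, also a mitotic gene, at 2.82.

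Macrophage identity genes rose as a list, with 14 of 29 higher and 7 lower (14 and 8 adjusted over the list alone) and a median of 0.78. Its camera adjusted p was 0.018, and 0.235 with an estimated correlation. The call was also lost without the 10 genes with the most counts, an alternative chosen after the data were seen (adjusted p = 0.162). Lyz1, a lysozyme, rose from 3240 ± 61.7 to 33150 ± 7415 CPM and the Fc receptor gene Fcgr3 from 8.27 ± 1.12 to 66.8 ± 3.68 CPM (SD, n = 3 each), both uncertain because Lyz1 shares sequence with Lyz2 and Fcgr3 with Fcgr2b. The scavenger receptor Cd36 and the Fc receptor Fcgr1 had log2 fold changes of -1.77 ± 0.11 and -1.91 ± 0.13. Of 18 genes of MHC and antigen presentation 7 were higher and 3 lower, the same adjusted over the list alone (median 0.13, or -0.08 with the length correction, camera adjusted p = 0.227, fry adjusted p = 0.0365), with H2-DMa at 2.50, Cd74 at 1.41 and Nlrc5 at -1.69. Of 12 alternative activation genes 2 were higher and 3 lower, the same adjusted over the list alone (median 0.43, mean 0.05, camera adjusted p = 0.923 with a negative sign). Over the alternatives the list median lay between -0.58 and 0.66. Gas6 was at 5.27, or 6.76 without control replicate 2, and Stab1 at -1.87.

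Genes of proliferation and mitosis rose in the libraries labelled RhoA knockout, in which Rhoa was not lower. Of 40 members 32 were higher, 1 lower and 7 not called (33 and 1 adjusted over the list alone), with a median of 1.42. Camera gave an adjusted p of 5.95e-15, and 0.309 with an estimated correlation. Ccnb2, a mitotic cyclin, rose from 9.12 ± 2.95 to 74.9 ± 0.745 CPM, Cdk1 from 38.3 ± 6.70 to 132.9 ± 9.60 CPM and the replication clamp Pcna from 67.6 ± 4.03 to 176.8 ± 11.9 CPM (SD, n = 3 each). Of 28 p53 target genes 4 were higher and 11 lower (4 and 13 adjusted over the list alone; median -0.80, camera adjusted p = 0.109, fry adjusted p = 0.00434), with the cell cycle inhibitor Cdkn1a at -1.49 ± 0.16.

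Genes of energy metabolism rose too. Of 45 nuclear-encoded oxidative phosphorylation genes 42 were higher and none lower, the same adjusted over the list alone, with a median of 0.92. For the list, camera gave an adjusted p of 3.90e-17, and 0.309 with an estimated correlation. Atp5o and Atp5c1, subunits of the ATP synthase, rose from 127.1 ± 9.33 to 509.8 ± 68.3 CPM and from 93.6 ± 6.24 to 318.0 ± 24.5 CPM (SD, n = 3 each). These genes are short, with a median exon length of 1908 bp, and short genes lay higher in the libraries labelled RhoA knockout in general, as given with the length trend. Of 31 glycolysis and hypoxia genes 18 were higher and 7 lower, the same adjusted over the list alone, with a median of 0.66. The camera adjusted p was 0.000149, and 0.425 with an estimated correlation. Tpi1 and Pfkl, glycolytic enzymes, rose by 2.21 ± 0.17 and 2.11 ± 0.11 on the log2 scale. Of 24 cholesterol synthesis and uptake genes 10 were higher and 3 lower (10 and 4 adjusted over the list alone; median 0.43, camera adjusted p = 0.153, fry adjusted p = 0.0207), with Fdps at 1.48. Of 10 cholesterol efflux and LXR target genes 2 were higher and none lower, the same adjusted over the list alone (median 0.21, camera adjusted p = 0.153, fry adjusted p = 0.0141), with the exporter Abcg1 at 2.56.

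Stress response lists went down or both ways. Of 20 NRF2 target and heme handling genes 15 were lower and 1 higher, the same adjusted over the list alone, with a median of -1.29. Its camera adjusted p was 3.45e-05, and 0.309 with an estimated correlation. Gclm, a subunit of the enzyme that limits glutathione synthesis, fell from 11.8 ± 1.21 to 1.21 ± 0.403 CPM, and Txnrd1, a thioredoxin reductase, from 30.1 ± 3.69 to 9.75 ± 0.563 CPM (SD, n = 3 each). Of 25 integrated stress response genes 16 were lower and 4 higher (17 and 4 adjusted over the list alone), with a median of -0.57. Camera gave an adjusted p of 0.0018, and 0.317 with an estimated correlation. Cth, an enzyme of cysteine synthesis, had a log2 fold change of -3.26 ± 0.13, and Chac1, which degrades glutathione, of 2.56 ± 0.20. Of 21 ER chaperone and unfolded protein response genes 7 were higher and 7 lower (7 and 8 adjusted over the list alone; median -0.27, camera adjusted p = 0.961 with a positive sign), with Herpud1 at 1.89 and Sel1l at -1.83. Of 14 heat shock genes 3 were higher and 8 lower, the same adjusted over the list alone (median -0.38, camera adjusted p = 0.153, fry adjusted p = 0.00467), with Hsph1 at -1.32. Of 46 cytosolic ribosomal protein genes 18 were higher and 6 lower, the same adjusted over the list alone (median 0.16, camera adjusted p = 0.11, fry adjusted p = 0.0442). The camera adjusted p was 0.00841 with library totals alone and 0.0298 without knockout replicate 2, and the median turned to -0.22 with the length correction. Rpl4 rose by 1.08 ± 0.12, and Rps2, at -3.49, is uncertain because 19 matching genes each held at least 10% of its count in a library.

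Measures of RNA makeup differed between the groups as well. Mitochondrially encoded genes went apart, with 10 of 15 higher and 4 lower, the same adjusted over the list alone, and a median of 0.93. For the list, camera gave an adjusted p of 2.48e-06, and 0.317 with an estimated correlation. With the length correction the list median was 0.47 (camera adjusted p = 0.0102). While mt-Nd1 and mt-Cytb rose steeply, mt-Co1 had a log2 fold change of -1.32 ± 0.13, mt-Rnr1 of -2.02 ± 0.29 and mt-Co3 of 0.16 ± 0.12 (adjusted p = 0.34, or -0.31 with an adjusted p of 0.0479 after the length correction), the last 3 chosen after their values were seen. Of these, mt-Co1 and mt-Co3 are uncertain because of their pseudogene copies Gm29216 and Gm28437. The mitochondrial share of counts was 8.68, 8.69 and 7.01% in the control libraries and 12.26, 11.89 and 9.95% in the others. All 5 measured structural small or nuclear RNAs fell, also adjusted over the list alone, with a median of -4.04, which is the value of the sparsely counted Rn7sk. The camera adjusted p was 0.00257, and 0.21 with an estimated correlation. Of the 5, Rn7s1 and Rn7s2, at 0.918 and 0.858 CPM in the controls, are identical over 300 bp and uncertain, and may hold the same reads. Taken as a single gene, they would leave the list under the minimum of 5 members for a test. The most abundant member, Malat1, held 7.91, 7.31 and 6.8% of the counts of the control libraries and 5.0, 5.64 and 6.06% of the others. Rn7sk, which holds an elongation factor inactive, fell from 4.40 ± 0.622 to 0.268 ± 0.179 CPM but is uncertain because of its copy Gm24447, and the nuclear Neat1 fell from 395.6 ± 41.5 to 136.4 ± 17.1 CPM (SD, n = 3 each), a log2 fold change of -1.54, or -0.72 with the length correction. Of 18 replication-dependent histone genes 3 were higher and 2 lower, the same adjusted over the list alone (median 0.28, camera adjusted p = 0.923). Over 3771 abundant protein-coding genes the median log2 fold change was 0.56 in the shortest eighth and -0.43 in the longest, with a Spearman correlation across genes, which are not independent replicates, of -0.32.

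**Figure D4:**
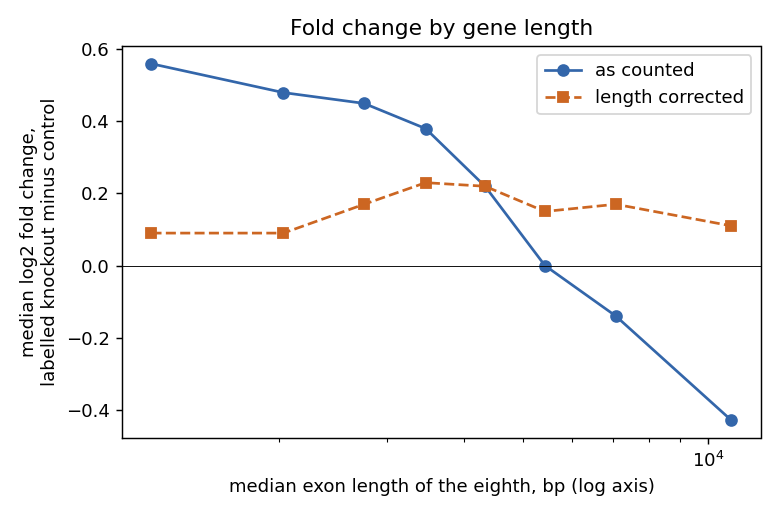
Median log2 fold change, libraries labelled RhoA knockout minus control, against median exon length on a log axis for eighths of 3771 abundant protein-coding genes. The solid line is the counted data, from 0.56 to -0.43, and the dashed line the values after a length correction in every library.

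Markers of other cell types were few. No list of such markers reached 5 measured members, so none was tested. Measured members numbered 1 of 14 for fibroblasts, 3 of 11 for osteoblasts, 3 of 14 for T cells, 1 of 13 for B cells, 3 of 13 for dendritic cells, 3 of 13 for neutrophils and none of 12 for epithelial cells. Ighm, an immunoglobulin chain, rose from 15.9 ± 2.33 to 30.2 ± 1.73 CPM (SD, n = 3 each), and Irf8, which macrophages also express, fell as above. Bglap2, an osteocalcin gene, held no counts in the control libraries and 46, 30 and 62 in the libraries labelled RhoA knockout, at least 36.2-fold higher against a floor of 3 counts over the control group, and is uncertain because it shares sequence with Bglap and Bglap3. Il7r had a log2 fold change of -1.27 at 1.72 CPM in the controls. Its call was lost without control replicate 1 or 3 or knockout replicate 2 or 3 (adjusted p = 0.0554, 0.204, 0.087 and 0.119), and with upper-quartile factors, library totals alone or a replicate block (0.0505, 0.0984 and 0.0836). Pdgfrb, Cebpe and Csf3r were not called (adjusted p = 0.21, 0.167 and 0.0883), though Pdgfrb passed without control replicate 2 (0.0332) and Cebpe with the length correction (0.0463). Csf3r is uncertain because of its pseudogene copy AC105061.2.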

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

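The length correction, the removal of the 10 genes with the most counts and the division of counts by 4 were chosen after the data were seen. Genes called numbered 5592, and between 4845 and 5313 when 1 library was left out. Tested against a 1.5-fold change, 3160 genes were called, 1458 higher and 1702 lower, as that test asks for a larger change. All other alternatives called between 5180 and 5907 genes. Of the 5592 genes, 4430 were called after the length correction, 4427 of them in the same direction. Leaving out 1 library gave 2286 to 2673 higher and 2403 to 2640 lower genes. The log2 fold change of Rhoa lay between 0.34 and 0.45 when 1 library was left out, with the adjusted p above 0.05 without control replicate 1 or knockout replicate 1, where fewer samples were tested, and reached 0.74 after the length correction. Camera called 12 lists at a preset correlation, 2 with an estimated correlation and 25 were called by fry, which asks another question. Same-numbered libraries did not deviate together over all genes (correlations of -0.01, 0.03 and 0.01). A batch shared by number is not excluded by this, as replicate 3 had the lowest mitochondrial share in both groups (7.01 and 9.95%). With the replicate block 5372 genes were called. Of 2579 comparisons of 144 further named genes with their alternatives 2566 kept direction and side of the threshold, 11 lost the call, 2 gained it and none reversed, and the cause was not tested. Most named genes were picked for small p-values or large changes, so they were likely to keep their calls. Of all 5592 called genes, 645 to 956 were no longer called when 1 library was left out, and 797 with library totals alone. Changes of 1.5-fold were recovered in 11.5% of simulated cases, with 200 changed genes per data set drawn from genes above a minimum expected count. The real comparison called 5592 genes, which loosens the cutoff of the adjustment, so that share does not carry over to it. How many changes of that size were missed is not known.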

Other observations

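The tests of gene families in this part, of scaling, of Rhoa copies and of exchanged labels, and the length correction, were chosen only after the results were seen. Families of genes with a shared symbol stem, some of which overlap the fixed lists, were tested as well. Of 175 families with at least 8 tested members camera called 16 at a preset correlation of 0.01, none with an estimated correlation, and 7 in the same direction after a length correction as well. The Ccl chemokines stood out with 8 of 9 lower and a median log2 fold change of -6.64 (adjusted p = 1.29e-21 before and 5.41e-28 after the length correction), and 7 of them are in a fixed list. Mitochondrial ribosomal proteins of the large subunit, in no fixed list, had 30 of 49 members higher and 2 lower in the libraries labelled RhoA knockout, in which Rhoa was not lower (median 0.47, adjusted p = 0.00012), with a median of 0.22 after the length correction (0.0371). Genes with the symbol stem Mcm had 5 of 10 higher and none lower (median 0.87, camera adjusted p = 0.0116), and 6 of the 10 are in fixed lists. Bcl genes had 9 of 17 lower and 1 higher (median -1.02, adjusted p = 0.017), and 2 of the 17 are in fixed lists.

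The fall of the type I interferon and inflammatory lists may reflect a state of the cells, but 2 technical explanations were tested first. If a few genes taking most of the counts caused it, the median of all genes would move with the scaling by as much as the lists did. It moved by 0.18 over 4 scalings, against list medians of -2.24 and -2.27. After a length correction in every library the higher of the 2 medians was -2.32 and both lists were still called, which argues against gene length as the cause. The edit, the Cas9 treatment itself, differences between the samples and any difference in handling go with the groups and stay open, untested.

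The rise of the oxidative phosphorylation list coincides with the trend of short genes. A gene length bias could give part of it, since the median fell from 0.92 to 0.55 with the length correction. The list was still called (camera adjusted p = 2.79e-09 at the preset correlation), and 40 of 45 members lay above 0 with quartiles of 0.31 and 0.92. A set of 903 other abundant protein-coding genes, with exon lengths between the list's quartiles of 1131 and 2634 bp, had a corrected median of 0.10. This argues against the trend with exon length as the whole cause. Exon length counts all annotated exons of a gene, not the transcripts expressed, so a bias by transcript length was not excluded. The shift of 0.18 in the median of all genes between scalings was too small to give the rise. What made the length trend, which is shared by all 3 libraries of each group, stays open, as does a biological difference.

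Rhoa was not lower in the libraries labelled RhoA knockout, and 3 explanations were weighed. Copies of Rhoa are unlikely to hold its reads, as the highest share of its count found at a matching transcript was 0.24%. A swap of single libraries between the groups is argued against by the library correlations, since 6 of 6 libraries correlated better with their own group. An exchange of the labels of both groups as a whole cannot be told apart from the labels as given, because a log2 fold change of 0.41 for Rhoa would be small for a loss of the gene in either direction. A frameshift edit that leaves the transcript in place stays open and was not tested, as the counts per gene do not show the edited site.

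The 6 libraries can be split 3 against 3 in 10 ways. The split by label called 5592 genes and the highest of the others 0, and 1 of the 10 splits gave as many genes. Each of the other splits mixes both groups, so the difference between the groups adds to the spread within each side and few genes can pass. The contrast with these splits therefore says nothing about chance. For lists the split by label called 12 and the highest of the others 10, and 1 of the 10 gave as many. With 10 splits no share under 0.05 can be reached.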
